A study of Arabidopsis thaliana with 6 samples.

How the data were processed

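Gene expression was measured on 6 Affymetrix arrays from Arabidopsis thaliana cotyledons that carried a YFP fusion of SEOR1, a sieve element protein, under the SEOR1 promoter. Per the labels' protocols, seedlings were grown for 6 days, and the cotyledons were then cultured for 72 hours with 2,4-D at 1.25 mg/L, kinetin at 0.25 mg/L and bikinin at 10 µM. The culture system is known as VISUAL and turns mesophyll cells of the leaf into vascular cells; 2,4-D is a synthetic auxin, kinetin a cytokinin, and bikinin an inhibitor of GSK3-like kinases. Protoplasts were then sorted by YFP into YFP-positive cells, which the series' design text calls phloem, and YFP-negative cells, which it calls non-phloem. Each group had 3 arrays, numbered 1 to 3 in the sample titles. Per the labels' protocols, total RNA was amplified with the NuGEN Ovation system and labelled with biotin. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The SEs given rest on that spread as well as on the number of arrays.

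The authors deposited 1 table of log2 values, made with RMA per the submitters' processing notes, whose version and settings are not given in the sources used here. The log2 scale was taken from the values, which ran from -0.11 to 13.39, and from RMA's usual output. The table held 38408 probe sets. Array medians were 2.55, 2.10 and 2.80 in YFP-negative replicates 1 to 3 and 2.61, 2.20 and 2.92 in YFP-positive replicates 1 to 3. Values matched in distribution between arrays of the same number, with a mean absolute difference of sorted values of 0.020, 0.085 and 0.038 for numbers 1 to 3, and differed by 0.157 to 0.551 between arrays of different numbers. These values argue against 1 joint quantile normalization of all arrays. How arrays of different numbers were set on a common scale stays unknown. Differences within each number are therefore given beside the pooled ones where they decide a statement. Exactly equal values (tolerance 0) were shared by both arrays of a number for 13489, 1961 and 1860 probe sets.

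Genes were named through a table that pairs probe sets with the platform's annotation, with symbols updated by gene ID through the RefSeq gene table of assembly TAIR10.1, from which 16411 of 16550 gene IDs matched. Of the probe sets, 16722 had exactly 1 gene, 759 had several and were not used for named genes, and 20927 were not named here. Most named genes carry a locus tag as their symbol, and the tag counted as a symbol in the rule below. SEOR1 and APL were to be reported in every case, and their probe sets are among those not named here, so their difference was not analysed here. For the same reason only 26 of the 227 members of the 12 marker lists were measured under a name. No coordinates are printed, because no build is named for the array table. The probe set with the highest mean stood for each of the 146 genes with several probe sets. In 1 of these genes at least 1 probe set passed the threshold, and in no gene did a called probe set stand beside one of the opposite sign.

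Differences were computed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as YFP-positive minus YFP-negative on the log2 values as deposited, two-sided, with Benjamini-Hochberg adjustment over 16550 genes and a threshold of 0.05. A second count required at least 2-fold. No filter on dim genes was used. Gene lists with at least 4 measured members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 41 lists; camera with an estimated correlation and fry were run beside it. The marker lists were fixed before the data were examined, as were the organelle lists, by locus. The reference gives no product names, so lists of cytosolic ribosomal proteins and histones by locus, and 35 families of at least 8 genes sharing the leading letters of their symbols, were set after the table was opened and before any difference was computed, and a family of shared letters can join unrelated genes; a proteasome list was not run. In place of the planned rule by locus, chloroplast genes were taken by the reference's chromosome. Mitochondrial genes were taken by symbols beginning with nad, cox, ccb, matR or atp1 whose gene IDs the reference lacks. This choice by symbol was made after the reference was opened, and it leaves out any mitochondrial genes with other symbols.

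Genes were named by a rule fixed before the data were examined. It took the 10 genes with the largest absolute log2 difference in each direction among those past the threshold, with a symbol and with groups that did not overlap. It also took from each fixed list the 3 members with the largest difference among those past the threshold, or, where none passed, the member with the smallest p. Genes outside this rule were chosen after their values were seen.

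The replicate numbers come from the sample titles. Deviations from the group means correlated across genes at 0.664, 0.607 and 0.489 between the same-numbered arrays, so the numbers pair the arrays. The equal values within a number go with shared processing. Whether shared samples also paired the arrays was not tested. The fit with the replicate number as a block was run beside the unblocked one and called 90 genes. Other alternatives were an intensity trend or a robust prior for the variance, leaving out the dimmest 30% of genes, quantile normalization, centring on each array's median, the mean of a gene's probe sets, every probe set as a row (with any control probe sets, which the tables used do not mark), a threshold of 0.01, ranked differences for lists, and leaving out each array. Alternatives chosen after seeing the data were the block with quantile normalization, leaving out both arrays of number 2, leaving out the 8432 genes with equal values on both arrays of any number, the block with an estimated correlation for lists, and the CYP symbols without those that the reference's synonyms call cyclophilins.

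The fit was tested on simulated values for the same 16550 genes with their own spread. Noise was drawn separately for each array, and a shift shared by same-numbered arrays was added only for the fit with the block. Equal values were not simulated, so the counts, above all those without the block, may not carry over to these arrays. Without the block it called 0%, 30%, 70% and 86% of genes changed by 1, 2, 4 and 6 on the log2 scale, and 4 unchanged genes. With the block it called 0%, 36%, 62% and 88%, and 3 unchanged genes.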

Results

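The data were 6 arrays, 3 of YFP-positive and 3 of YFP-negative protoplasts, sorted from cotyledons after 72 hours in the induction medium. The sort was by the YFP signal of SEOR1-YFP, a sieve element protein, and the comparison asked which transcripts distinguished YFP-positive cells, called phloem in the design text, from the YFP-negative cells beside them. How well the sort parted them was not checked by SEOR1, which was not analysed here. Across named genes, arrays of the YFP-positive group correlated at 0.949 to 0.958 with each other, and arrays of the YFP-negative group at 0.894 to 0.926. Same-numbered arrays of opposite groups correlated at 0.949, 0.907 and 0.895 for numbers 1 to 3, so that in number 1 the value across groups was above each value within the YFP-negative group. These correlations are across genes, which are not independent replicates.

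AT4G05430, which encodes a protein with an X8 carbohydrate-binding domain, stood at 10.15 on the log2 scale in YFP-positive cells and at 1.62 in YFP-negative cells, and RR16, a type-A response regulator induced by cytokinin, was 11.8-fold higher in YFP-positive cells. YFP-negative cells held more of AT1G26390, a berberine bridge enzyme-like oxidoreductase, at 9.82 against 2.95, and of ChiC, a class V chitinase, by 30.6-fold. In all, 179 of 16550 genes differed in limma at an adjusted p under 0.05, 142 higher and 37 lower in YFP-positive cells, and all 179 differed at least 2-fold. The median log2 difference was 4.83 among the higher genes and -3.19 among the lower genes. With the replicate number as a block, limma called 90 genes, and both fits called 58 of the 142 and 5 of the 37. AT4G05430, RR16 and ChiC passed with the block, and AT1G26390 did not (adjusted p = 0.0835). For 53 of the 142 higher genes, AT4G05430 included, every YFP-negative value lay under the median of its array, and for 5 of the 37 lower genes every YFP-positive value did. Of the 3 YFP-positive values of AT1G26390, 1 was under that median. Signal over background was not analysed here, so no fold is given for AT4G05430 or AT1G26390, and a log2 difference against such dim values is a difference of deposited values whose size in transcript level, and so its rank, stays unknown.

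Among the 10 genes with the largest higher values, AT4G05430 averaged 10.15 ± 0.48 (SD, n = 3) on the log2 scale in YFP-positive cells and 1.62 ± 0.32 (SD, n = 3) in YFP-negative cells. Its log2 difference was 8.54 with an SE of 0.34 and an adjusted p of 0.0017 from limma, and its pair differences were 8.30, 8.28 and 9.03. AT1G61760 and AT4G05220, both of a late embryogenesis abundant hydroxyproline-rich glycoprotein family, had log2 differences of 7.97 (SE 0.40) and 7.87 (SE 0.36). AT3G05620, a pectin methylesterase, a class of enzyme that de-esterifies cell wall pectin, differed by 7.84 (SE 0.41). The F-box gene AT5G67040 stood at 8.69 ± 0.43 (SD, n = 3) against 1.02 ± 0.09 (SD, n = 3), a log2 difference of 7.66. AT3G01940 stood at 11.75 ± 0.26 (SD, n = 3), against 4.16 ± 0.83 (SD, n = 3). AT5G38080, AT5G50290, AT4G00890 and the ankyrin repeat gene AT5G04700 differed by 7.02, 6.92, 6.80 and 6.84. In AT4G05430, AT1G61760, AT4G05220, AT3G05620 and AT5G67040 every YFP-negative value lay under the median of its array, and 4 of the other 5 had at least 1 such value, all but AT3G01940, so the order of the 10 is not settled. With the replicate number as a block, 7 of these 10 passed, and AT5G38080 (adjusted p = 0.0542), AT4G00890 (0.0597) and AT5G04700 (0.126) did not. In AT5G04700 the pair differences were 9.16, 3.81 and 7.57.

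Among the 10 genes with the largest lower values, AT1G26390 averaged 2.95 ± 1.60 (SD, n = 3) in YFP-positive cells and 9.82 ± 1.05 (SD, n = 3) in YFP-negative cells, a log2 difference of -6.87 with an SE of 0.91 and an adjusted p of 0.0323 from limma. The glycine-rich protein gene AT4G21620 differed by -5.76 (SE 0.73), and the dirigent-like gene AT1G22900 by -5.51 (SE 0.57). ChiC differed by -4.94 (SE 0.60), and AT4G16260, a beta-1,3-glucanase of glycoside hydrolase family 17, by -4.70 (SE 0.65). AT1G51920, AT3G57020, AT3G13433 and AT5G20790 differed by -5.09, -4.41, -4.30 and -4.21. CLE14, which encodes a signalling peptide of the CLE family, stood at 2.54 ± 0.83 (SD, n = 3) against 6.72 ± 0.94 (SD, n = 3), a difference of -4.18 with an adjusted p of 0.0476. With the replicate block, ChiC and AT5G20790 passed at 0.0452 each, and the other 8 did not, at adjusted p-values from 0.0542 to 0.126. The pair differences of the 10 ran from -2.26 in pair 1 for CLE14 to -8.55 in pair 2 for AT1G26390. Except for ChiC and AT3G13433, each of the 10 had at least 1 YFP-positive value under the median of its array, and AT1G51920, AT4G16260 and AT3G57020 had 2, so the order of these differences is not settled either. Over the 17 alternatives each of the 10 passed in 6 (CLE14) to 15 (AT5G20790).

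**Figure D1:**
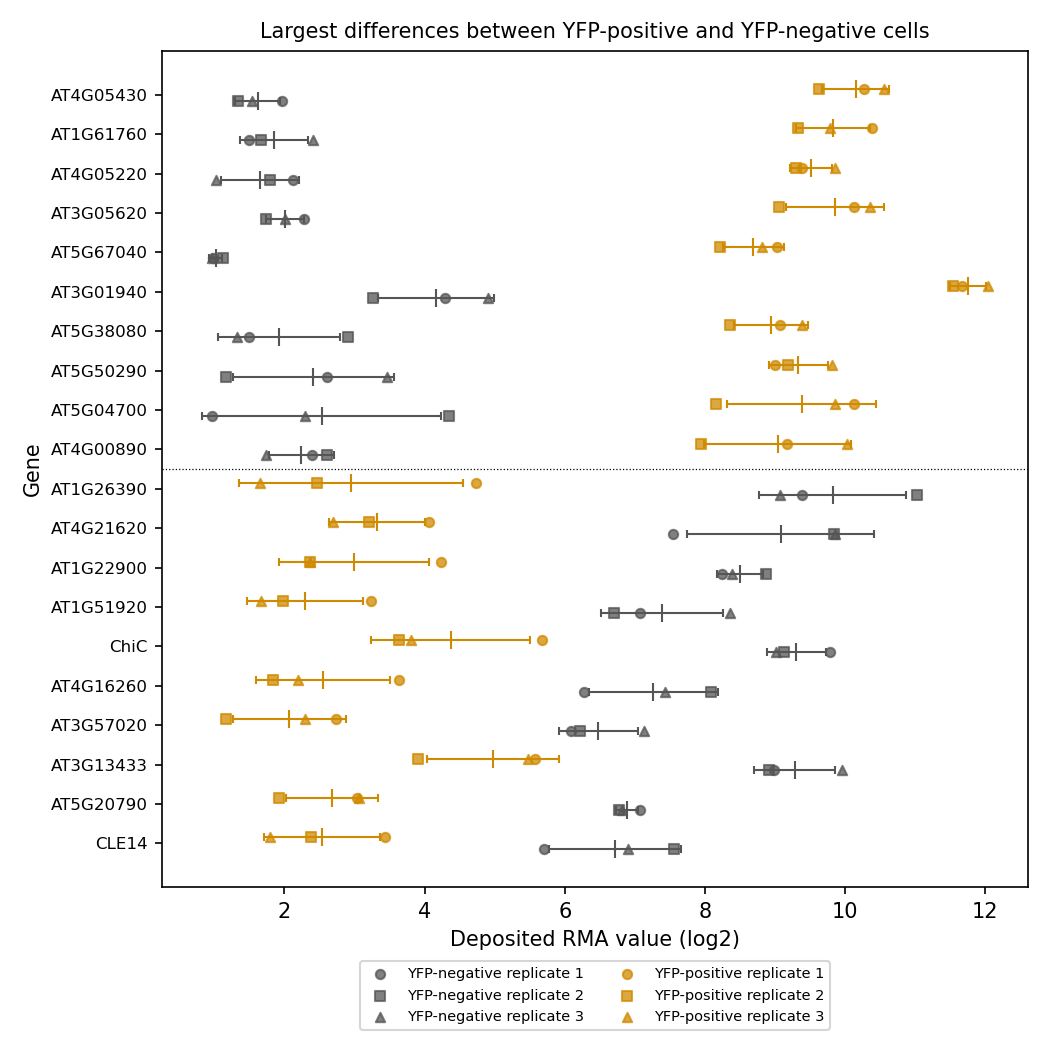
Deposited log2 values (horizontal axis) of the 20 genes with the largest differences (vertical axis), 10 higher above the dotted line and 10 lower below it. Grey symbols are YFP-negative and ochre symbols YFP-positive arrays, the symbol shape gives the replicate number, and vertical ticks with bars are group means and SDs (n = 3). The genes were chosen among those whose groups do not overlap, and their log2 differences run from 8.54 for AT4G05430 to -6.87 for AT1G26390.

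With the replicate block limma called 90 genes, 82 higher and 8 lower, of which 63 were also called without the block, and 2279 genes had an unadjusted p under 0.05 against 1318 without it. Without YFP-negative replicate 3 the count was 38 and without YFP-positive replicate 3 it was 37, with 0 lower genes in either (464 and 404 lower genes had an unadjusted p under 0.05 in limma). Leaving out YFP-positive replicate 1 left 81 genes, 46 higher and 35 lower (56.8% higher against 79.3%), and leaving out YFP-positive replicate 2 left 94, 91 higher and 3 lower (96.8% higher); without YFP-negative replicate 1 the higher genes numbered 86, and without YFP-negative replicate 2 the lower genes numbered 13. Centring each array on its median gave 316 higher and 165 lower genes, a share of 65.7% higher against 79.3%. That centring also moved the median log2 difference of all genes from -0.04 to -0.16. YFP-negative replicate 2 stood apart: 80 genes over 4 higher on the log2 scale in pairs 1 and 3, and over 8 in every YFP-positive array, had a median gap of 3.37 in pair 2, where the same selection on the other pairs gave 7.27 in pair 1 (27 genes) and 6.59 in pair 3 (31 genes), and 126 genes were called without both arrays of that number. Groups did not overlap for 9.30% of all genes, against 0.84% to 1.02% in the 3 other splits of the arrays that part every same-numbered pair. The 10% that chance gives for 3 unrelated arrays against 3 is not the value to set this against, since same-numbered arrays deviate together and the 8432 genes with equal values on both arrays of a number cannot separate.

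Marker lists of cell types and hormone responses were sparsely represented among named genes. In the cytokinin response list, RR16 (listed as ARR16) was higher and ARR15 did not pass. RR16 averaged 9.03 ± 0.66 (SD, n = 3) in YFP-positive and 5.47 ± 0.39 (SD, n = 3) in YFP-negative cells, a log2 difference of 3.56 (SE 0.41) with an adjusted p of 0.0225, or 0.0401 with the block. Leaving out 1 array raised it to 0.0554 to 0.0841, except without YFP-positive replicate 2 (0.0431). ARR15 had a log2 difference of -1.09. With p-values adjusted over the list alone, 1 of the 2 passed.

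Among 4 measured early phloem regulators none passed over all genes, and 1 passed adjusted over the list alone. This was CLE45, a peptide gene of the protophloem, at 4.14 ± 0.59 (SD, n = 3) against 1.99 ± 0.48 (SD, n = 3), a log2 difference of 2.15 (SE 0.41) with an adjusted p of 0.0951. With the replicate block its adjusted p was 0.0444, and its pair differences were 2.2, 2.03 and 2.22. Every YFP-negative value of CLE45 lay under the median of its array, so the size of its difference in transcript level stays unknown. The DOF transcription factor gene AT5G02460 (PEAR2) had a log2 difference of 1.70, with pair differences of 1.08, 3.36 and 0.67, and of 0.80 without YFP-negative replicate 2. CLE26 and CLE25 had differences of 0.35 and 0.13, whose direction turned when 1 array was left out, for CLE26 to -0.07 without YFP-positive replicate 3 and for CLE25 to -0.28 without YFP-negative replicate 1 and -0.23 without YFP-positive replicate 3. Every CLE26 value lay under the median of its array. The list as a set had a median of 1.03 and an adjusted p of 0.059 in camera, and of 0.98 with an estimated correlation; within pairs 1 to 3 its medians were 0.58, 1.05 and 1.02. Its adjusted p came to 0.031 with quantile normalization and 0.033 with median centring, and to 0.048 without YFP-negative replicate 2 and 0.035 without YFP-positive replicate 1, within a range of 0.031 to 0.98 over the alternatives.

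In the lists of sieve elements, companion cells and phloem parenchyma, xylem, and procambium and cambium, no member passed over all genes. OPS, the only measured member of the sieve element list, had a log2 difference of 0.73 (SE 1.03), with pair differences of 0.29, 1.16 and 0.73. With the replicate block its SE was 0.23, and it passed adjusted over the list alone, which is this 1 gene, at an adjusted p of 0.0363 from limma, while its adjusted p over all genes was 0.307. Without the block its direction turned to -0.21 when YFP-negative replicate 2 was left out, which leaves the YFP-positive array of that number unmatched. In the other 3 of these lists no member passed adjusted over its list alone, with or without the block. The sucrose transporter SWEET11, the only measured member of the 11 in the list of companion cells and phloem parenchyma, had a difference of -1.25 (SE 1.62). Its pair differences were 0, -0.91 and -2.84. GUT2 (IRX10), a glucuronoxylan synthesis gene and the only measured member of the 30 in the xylem list, had a difference of -0.49 (SE 0.59). Its pair differences were 0, 0.81 and -2.29. Among 3 measured genes of procambium and cambium, the receptor kinase gene MOL1 had the smallest p, with a difference of 0.52 (SE 0.42). Every MOL1 value lay under the median of its array, and its pair differences were 0, 0.52 and 1.04.

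The few measured markers of the cell types that the YFP-negative gate could hold, and of stress and division, gave no call, over all genes or adjusted over their list alone. Measured were 6 of 37 nuclear photosynthesis genes, 2 of 20 of epidermis and guard cells, and 3 of 28 of the cell cycle. For wounding, jasmonate and stress it was 1 of 23, and for auxin response 2 of 5. So few members cannot speak for these cell types or responses as a whole. Of 6 nuclear photosynthesis genes 5 had negative differences, with PSBW, a photosystem II subunit, at -1.13 (SE 0.41) and RCA at -0.71. The list had a median of -0.49 and an adjusted p of 0.17 in camera, and of 0.98 with an estimated correlation. The guard cell regulators FMA (FAMA) and MUTE differed by -1.17 and -0.26. The pair differences of FMA were 0, -0.41 and -3.09, and its highest value, 5.42, was on YFP-negative replicate 3. Its difference therefore came mostly from pair 3. Every MUTE value lay under the median of its array, and its pair differences were 0, 0 and -0.78. PRL (MCM7) had the smallest p of 3 cell cycle genes, at -0.21 (SE 0.37), and the stress gene STZ (ZAT10) differed by -0.52 (SE 0.32). The auxin-induced genes GH3.3 and IAA29 differed by -0.72 and -0.97. No member of the brassinosteroid synthesis list was analysed here.

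Of 63 chloroplast-encoded genes 60 had negative differences, with a median of -0.45. The set had an adjusted p of 1.8e-05 in camera with the preset correlation (9.4e-06 with the replicate block), but the call was lost with an estimated correlation (adjusted p = 0.98, or 0.87 with the block), and fry gave 0.92. Singly 0 passed in limma, over all genes or adjusted over the list alone. Among them rbcL, the large subunit of Rubisco, had the smallest p, with 6.28 ± 0.31 (SD, n = 3) against 7.63 ± 0.34 (SD, n = 3) and a difference of -1.34 (adjusted p = 0.155). The medians within pairs 1, 2 and 3 were 0.00, -0.37 and -0.95. In pair 1, 31 members lay below 0, 27 above, and 5 had equal values on both arrays. The pooled median was -0.51 with quantile normalization and -0.56 with median centring.

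All 16 mitochondrion-encoded genes of the list had negative differences, with a median of -0.50, or -0.61 with quantile normalization and -0.62 with median centring. The set had an adjusted p of 0.012 in camera, of 0.054 with the replicate block and of 0.98 with an estimated correlation. Its medians within pairs 1 to 3 were -0.05, 0.03 and -1.58, so the shift lay in pair 3, and the adjusted p was 0.29 without YFP-negative replicate 3 and 0.69 without YFP-positive replicate 3. The gene ccb382 had the smallest p, at -0.68 (SE 0.31). No member passed singly, neither over all genes nor adjusted over the list alone.

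Of the 35 symbol families 1 passed, that of symbols beginning with CYP, which joins 26 cytochrome P450 symbols with 2 cyclophilins, CYP71 and CYP59. Most of the 26 carry CYP71B symbols, so the list does not stand for cytochrome P450 genes in general. Whether related members share probe signal was not tested. Of these 28 members 20 had negative differences, with a median of -0.36 (-0.40 with quantile normalization, -0.47 with median centring), an adjusted p of 0.0093 in camera, 0.053 with the replicate block and 0.98 with an estimated correlation. Without the 2 cyclophilins, a choice made after seeing the data, 19 of the 26 had negative differences, with a median of -0.41 (-0.52 with quantile normalization, -0.53 with median centring), an adjusted p of 0.0037 in camera, 0.024 with the block and 0.98 with an estimated correlation. No member passed over all genes, and 1, CYP71B20, passed adjusted over the list alone. CYP71B20, CYP71B23 and CYP71B22, named after their values were seen, differed by -1.56, -3.50 and -3.06. Their adjusted p-values in limma were 0.0774, 0.218 and 0.362. The pair differences of CYP71B22 were 0, -4.05 and -5.14. Several members were dim in both groups, such as CYP71B16 (1.23 in YFP-positive against 1.33 in YFP-negative cells) and CYP71B29 (1.27 against 1.46). Dim members also lay above 0, such as CYP71B37 (1.29 against 1.21). The counts of negative differences therefore include dim genes. In pairs 1 to 3 the medians of the 26 were 0.00, -0.34 and -0.65; in pair 1 the value is set by 13 members with equal values on both arrays, and the other members had a median of -0.30 there. The 26 no longer passed without YFP-negative replicate 2 (0.080), and the 28 neither then (0.080) nor without YFP-positive replicate 3 (0.090). None of the 41 lists passed fry or the estimated correlation.

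Cytosolic ribosomal protein genes, 139 in number, had a median difference of -0.05 and a mean of 0.01, and camera gave an adjusted p of 0.92 in the lower direction. AT5G09500 had the smallest p among them, with a difference of 3.0 (SE 0.80) that did not pass (adjusted p = 0.25). Of 12 histone genes 1 passed over all genes, AT2G28720, a histone H2B gene, lower at 5.21 ± 0.19 (SD, n = 3) against 6.84 ± 0.19 (SD, n = 3), with an adjusted p of 0.0495. It did not pass in 15 of 17 alternatives, the block (0.0528), quantile normalization (0.185), median centring (0.113) and each array left out in turn among them, within 0.0401 to 0.3. Adjusted over the list alone, 2 histone genes passed, and the list as a set did not (adjusted p = 0.81).

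**Figure D2:**
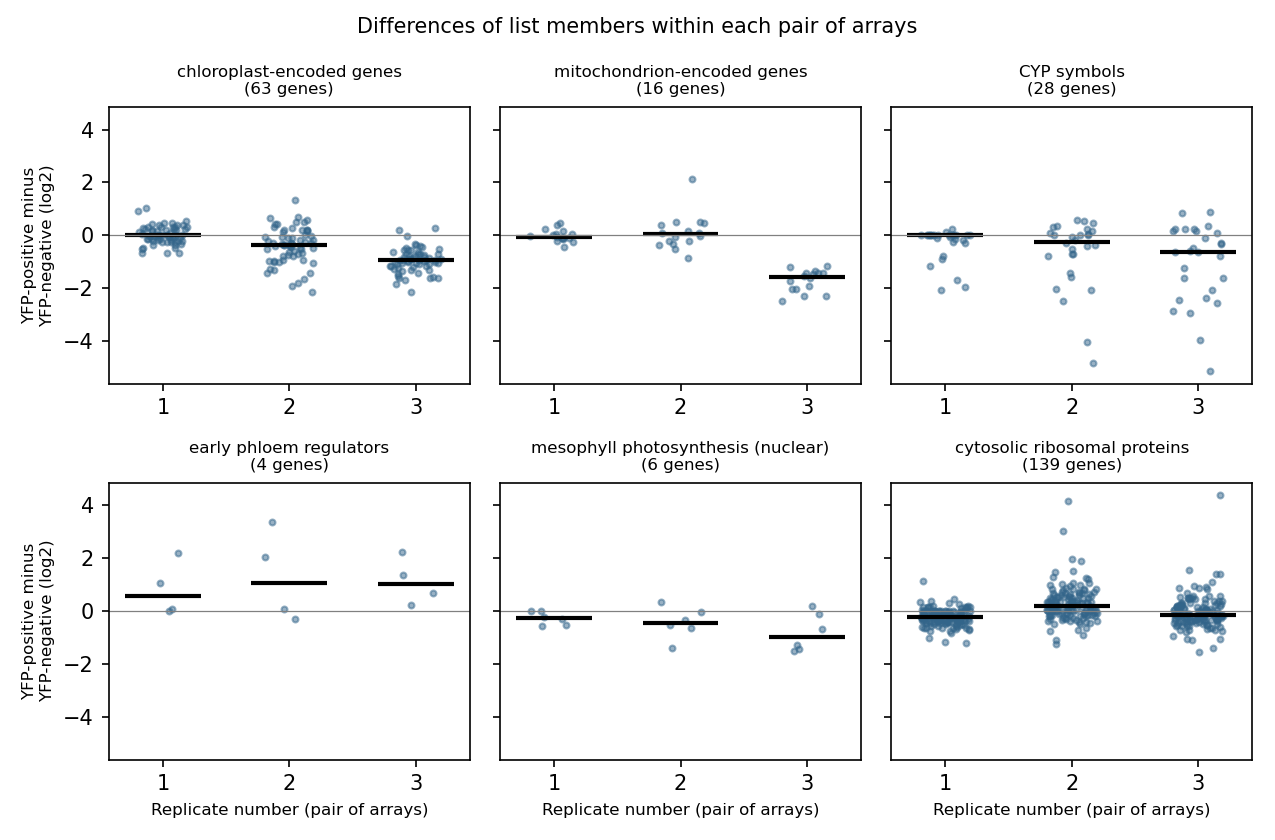
YFP-positive minus YFP-negative differences (log2, vertical axis) of the members of 6 gene lists within each of the 3 pairs of same-numbered arrays (horizontal axis); points are genes and black bars are medians. The chloroplast medians are 0.00, -0.37 and -0.95, the mitochondrial medians -0.05, 0.03 and -1.58, and 14 of the 28 CYP symbols have equal values, a difference of 0, in pair 1.

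Among the 20927 probe sets not named here, 113 passed when every probe set was tested, 89 higher and 24 lower in YFP-positive cells. Probe sets 13443945 and 13527333 had the largest higher differences, 7.11 and 6.89, and probe sets 13484924 and 13534934 the largest lower ones, -5.64 and -5.46. The first 2 averaged only 1.76 and 2.11 in YFP-negative cells, and 13534934 only 1.62 in YFP-positive cells, so this order is not settled.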

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

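Leaving out both arrays of number 2, leaving out genes with equal values on both arrays of a number, the block with quantile normalization, the block with an estimated correlation and CYP symbols without cyclophilins were chosen after seeing the data. The 179 genes, all at least 2-fold different (142 higher, 37 lower), became 90 (82 and 8) with the replicate block, 307 (242 and 65) with an intensity trend in the variance prior, 304 (224 and 80) without the dimmest 30% of genes, 481 (316 and 165) with each array centred on its median, and 324 (234 and 90) without genes of equal value on both arrays of a number. At a threshold of 0.01 limma called 37 genes, 37 higher and 0 lower, where 567 lower genes had an unadjusted p under 0.05. The block with quantile normalization gave 79 lower genes, and leaving out both arrays of number 2 gave 3. Leaving out 1 array gave 37 to 164 genes, at least 2-fold or in all, with 37 to 151 higher and 0 to 38 lower; fewer arrays enter each of these fits. The robust prior, quantile normalization alone, the mean of a gene's probe sets and every probe set as a row kept the total within 1.5 times. Of the 179 genes, 145 were shared with quantile normalization, 63 with the block and 35 and 37 without YFP-negative or YFP-positive replicate 3. The number of gene lists that passed, 3, was 1 with the replicate block, 5 with quantile normalization, 5 without both arrays of number 2, 0 with an estimated correlation with or without the block, and 1 to 4 when 1 array was left out. Early phloem regulators (adjusted p 0.059) came to 0.031 with quantile normalization, 0.033 with median centring, 0.039 without both arrays of number 2 and 0.035 to 0.26 without 1 array. Mitochondrial genes (0.012) came to 0.054 with the replicate block, 0.063 without genes of equal value on both arrays of a number and 7e-05 to 0.69 without 1 array, and CYP symbols (0.0093) to 0.053 with the block, 0.0037 without cyclophilins and 0.00075 to 0.09 without 1 array. With an estimated correlation mitochondrial, chloroplast and CYP lists came to 0.98, and to 0.87 with the block as well; chloroplast genes (1.8e-05) otherwise stayed under 0.05, at 1e-06 to 0.041 without 1 array. Ribosomal proteins (0.92, lower) turned to higher with ranked differences (0.96) and without YFP-negative replicate 1 (0.59), YFP-positive replicate 1 (0.87) or YFP-positive replicate 3 (0.48), within 0.065 to 0.99 without 1 array and reaching 1 with median centring. Among named genes below the threshold, OPS turned to -0.21 without YFP-negative replicate 2 (1.46 without YFP-positive replicate 2), and SWEET11, GUT2 and FMA to 0.33, 0.07 and 0.16 without YFP-negative replicate 3, with lowest values of -2.49, -0.85 and -1.85 when 1 array was left out. No named gene past the threshold changed direction in any alternative. Of the 20 largest differences, 9 stayed past the threshold with the replicate block, 18 with quantile normalization and 8 without either array of number 3. The cause was not tested for any of these changes beyond the smaller number of genes or arrays. The alternatives for SEOR1 were not run, since its probe set is not named here. Probe signal over background was not analysed here.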

Other observations

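All tests of hypotheses in this part were chosen after the patterns were seen, except those on splits of the arrays. Genes with a symbol other than a locus tag made up 10 of the higher and 8 of the lower genes, RR16, ChiC and CLE14 included, and the examples here were chosen after their values were seen. BGLU33, a member of the beta-glucosidase family, averaged 10.20 ± 0.79 (SD, n = 3) against 3.89 ± 0.48 (SD, n = 3), and AMY1, an alpha-amylase, 8.93 ± 0.79 against 4.50 ± 0.88. SIM, a cyclin-dependent kinase inhibitor known for promoting endoreduplication, was higher by 3.11 on the log2 scale (SE 0.35, adjusted p = 0.0208 in limma, 0.0333 with the replicate block). The tetraspanin gene TET6 was higher by 5.51, and the MADS-box genes AGL53 and AGL19 by 4.30 and 3.04; with the replicate block AGL53 passed (0.0216), and TET6 (0.0504) and AGL19 (0.0828) did not. BRH1, a RING finger gene that responds to brassinosteroid, was higher by 2.53 (adjusted p = 0.0467, and 0.0933 with the block).

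Lower in YFP-positive cells were the plant defensin PDF1.4, at 4.95 ± 0.75 (SD, n = 3) against 8.89 ± 0.07 (SD, n = 3), the pirin gene PRN, with a log2 difference of -3.45, and EFR, the receptor for bacterial elongation factor Tu, with -2.30. The zinc finger gene ZAT7 differed by -2.13. With the replicate block PRN and EFR passed at 0.0444 each, and PDF1.4 (0.056) and ZAT7 (0.0818) did not.

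Lower values of AT1G26390 and AT5G44380 raised the hypothesis that berberine bridge enzyme-like genes were lower as a family. A list of the family from general knowledge had 24 measured members, of which these 2 were called lower; with the replicate block neither passed (0.0835 and 0.0735). Of the 22 members not called, 20 had negative differences, with a median of -0.86, and the set had an adjusted p of 1.2e-07 in camera over the 3 families tested, 3.9e-05 with the replicate block and 0.029 with an estimated correlation. The median of these 22 was -0.75 with quantile normalization and -0.98 with median centring, and within pairs 1 to 3 it was -0.28, -0.84 and -1.10. AT1G26380 and AT1G30720, at -4.77 (adjusted p = 0.0547 in limma) and -4.25 (adjusted p = 0.15), had the largest differences of these 22. Several others, such as AT5G44360 (-0.02) and AT5G44440 (-0.01), barely differed and were dim in both groups. The set result goes with lower values in many members of the family, though not in each, and the hypothesis was tested on the data that raised it. Whether related members share probe signal was not tested.

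Chitinases gave a less settled picture. Of 17 members apart from ChiC, 12 had negative differences, with a median of -0.24 and an adjusted p of 0.00093 in camera, 0.0053 with the replicate block and 0.11 with an estimated correlation. The 5 members above 0, such as AT4G19800 (1.44 against 1.22), were dim in both groups. Several members below 0 were dim as well, among them AT4G19820 (0.91 against 1.15), whose difference is the median. The median is therefore that of a dim gene. Of brighter members, CHI, AT1G02360 and AT3G47540 differed by -2.46, -2.34 and -2.24, and none passed over all genes. AT2G43620 and AT2G43590 differed by -4.97 and -4.67 and did not pass (adjusted p = 0.113 and 0.172). For glycoside hydrolase family 17, whose members act on beta-1,3-glucans such as callose, 4 of 41 genes were higher and 1 was lower. AT3G15800 and AT5G20870 were higher by 6.78 and 6.58, AT1G66250 by 4.26 and AT1G32860 by 2.53, and with the replicate block none of these 4 passed, at 0.0504 to 0.0905. AT5G24318, higher by 5.11, passed with the block (0.0216) and not without it (0.054), and AT4G18340, at 4.96, passed in neither (0.0965, and 0.131 with the block). The 36 members not called without the block, these included, had 18 differences on each side of 0, a median of 0.01 (-0.11 with median centring) and an adjusted p of 0.27 in camera, 0.28 with the block. Whether the family was higher as a whole stays open.

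Genes next to each other on the chromosomes were called together. Of 175 called genes placed on the reference, 10 adjacent pairs of measured genes were called in the same direction, 9 higher and 1 lower, against a mean of 1.26 and a maximum of 7 in 10000 random draws (permutation p = 1e-04, the smallest that these draws can give). Among them were AT5G67040 and AT5G67050, with differences of 7.66 and 6.57, AT5G04690 and AT5G04700, with 6.56 and 6.84, and AT3G13432 and AT3G13433, with -3.54 and -4.30. Chance placement is argued against by the 10 pairs. Whether neighbours are duplicates that share probe signal or are regulated together was not tested.

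YFP-negative replicate 2 had intermediate levels of many genes of the YFP-positive cells. For 80 genes over 4 higher on the log2 scale in pairs 1 and 3 and over 8 in every YFP-positive array, the median gap in pair 2 was 3.37; the same selection on the other pairs gave 27 genes with a median gap of 7.27 in pair 1 and 31 genes with 6.59 in pair 3. A constant share of YFP-positive cells in that sort would put these genes at about the same fraction of their YFP-positive level, but fractions ran from 0.321% to 57.3% around a median of 9.70%, and 15% of the genes lay over 8-fold under it. The share that noise between arrays alone would give was not computed. After quantile normalization over all arrays the gap was 2.97, against 7.19 and 6.58 for the selections in pairs 1 and 3. It was 3.88 under the smaller gap of the 80 genes in the pairs they were selected on. Bringing all arrays to the same distribution thus left the gap in place. Both arrays of number 2 already matched in distribution, and this step cannot undo a separate summarization of probes. It therefore cannot decide whether separate normalization of number 2 played a part. Younger phloem cells without YFP stay open, since of 4 early phloem regulators only 1, CLE25, was higher on that array than on both other YFP-negative arrays and 2 were lower, too few to decide; a share of cells from a part of the YFP-positive population was not tested.

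Identical values tie together the arrays of each number. Same-numbered arrays shared 1860 or more exactly equal values of 38408, and any other pair of arrays at most 1, which is consistent with the arrays of each number having been summarized together and apart from the rest. Pair 1 shared 35.1% of its values, against 5.11% and 4.84% in pairs 2 and 3. That pair 1 was 1 RNA sample under both labels is argued against by its median gap of 7.27 for the 27 genes that were over 4 higher in pairs 2 and 3. No biological explanation was tested for the higher share in pair 1.

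Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 179 genes, at least 2-fold or in all, the highest of the other splits called 0 in limma, and so only 1 split gave as many. Among the other 3 splits that part all same-numbered pairs at most 62 genes had an unadjusted p under 0.05 in limma. The splits that part 1 pair reached 2304, against 1318 in the real split. This points to the numbers as a structure of the arrays, whether from the samples or from their processing. For gene lists, 5 of the 10 splits gave 3 or more lists, the real one included, and the highest of the others gave 6.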
